A study of Mus musculus with 6 samples.

How the data were processed

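Gene expression was measured by RNA sequencing in 6 samples of mouse aorta, 3 from ApoE-/- mice and 3 from IL16-/-ApoE-/- mice (called double mutants here), with the groups and the numbers 1 to 3 taken from the sample titles, in which the first group is written Apo-/-. Per the labels' protocols, RNA was extracted with TRIzol, polyadenylated RNA was captured on oligo(dT) beads and fragmented by heat, and strand-marking libraries of about 300 bases were made by digestion with UDG enzyme. The authors deposited one table of raw read counts per gene, with 1 column for each of the 6 samples and no normalization, as judged from its whole numbers and from column totals that differ between samples. Cutadapt, HISAT2 and StringTie are named, without versions, per the submitters' processing notes. The genome build, the annotation, the program that counted the reads and its strand setting are not given in the sources used here. Reads shared between a gene and its near-identical copies, such as processed pseudogenes of ribosomal protein genes, could be split between them by the counting, and counts of such genes are uncertain. The same holds for overlapping genes and for a gene and its antisense partner.

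The table held 55401 Ensembl gene IDs. Of these, 55141 matched a symbol and a position in the GENCODE M21 annotation of mouse assembly GRCm38, and 260 did not. IDs without a symbol held 0.00640% to 0.0114% of a library's counts. Positions and transcript lengths (the median over a gene's basic transcripts) come from that annotation and not from the authors' files.

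Library totals were 85568300, 65730600 and 84993200 counts for ApoE-/- 1, 2 and 3, and 43340300, 47208800 and 42862000 for double mutant 1, 2 and 3. The totals of the groups did not overlap. A count of 0 allows up to 3 counts, which is 0.0358 to 0.0430 CPM in a single ApoE-/- library and 0.0630 to 0.0698 CPM in a double mutant library. Where all 3 ApoE-/- libraries held no count of a gene, the fold is a lower bound computed against 3 counts over the 3 libraries summed. These floors and bounds cover counting error only. The intervals given are exact intervals over genes or bootstrap intervals over genes, which treat genes as independent.

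Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), which left 19833 genes. Counts were scaled by TMM, dispersions were estimated with estimateDisp, and groups were compared with edgeR's quasi-likelihood test (glmQLFit with robust moderation and glmQLFTest, two-sided, no covariate), with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values are TMM-scaled, and log2 CPM for list means and correlations used a prior count of 2. The SE of a log2 fold change is its size divided by the square root of the quasi-likelihood F. Gene lists with at least 5 tested members were compared with all other genes by limma's camera with a preset inter-gene correlation of 0.01, adjusted over 32 lists. Camera with an estimated correlation and fry, which asks of a list alone whether its genes move on balance one way or (mixed test) in either direction, were run beside it. Genes within 10 Mb of Il16 were compared with all other tested genes that had a position by a two-sided Fisher's exact test, with Il16 itself left out. Computations used R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and figures Python 3.11.15 with matplotlib 3.10.9.

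The design, the 33 gene lists, the rule for named genes and the alternatives were set before the data were examined, except for those said below to be added later. The lists cover contractile and modulated smooth muscle, collagens and elastic matrix, matrix proteases, fibroblasts, endothelium and its adhesion molecules, macrophages, foam cells, T, B, NK and neutrophil cells, erythroid cells and platelets, cytokines, interferon response, MHC class II, inflammasome, ferroptosis and iron, adipocytes, brown fat, oxidative phosphorylation, fatty acid metabolism, cholesterol synthesis, skeletal and cardiac muscle, Schwann cells and neurons, cell cycle, immediate early genes, circadian clock, IL-16 receptors, Il16 neighbours and sex-linked genes, the last of which was not tested. By the rule, Il16 and Apoe are named always. Also named are the 10 genes with the largest positive and the 10 with the largest negative log2 fold change among those past the threshold with a mean CPM of at least 1, all 3 libraries of a group on one side and a symbol that is not a predicted or clone name. Only 5 genes qualified in the negative direction. From each list, up to 4 members past the threshold are named, or up to 2 of those with the smallest p where none passed and the list passed or is discussed. Marker lists of 4 nephron segments, liver, adrenal cortex, lung epithelium, exocrine pancreas and thymocytes were added after the largest changes had been seen.

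Alternatives were RLE and upper-quartile factors, library totals, no filter, a filter of at least 1 CPM in 3 libraries, DESeq2, limma-voom with and without sample weights, moderation without robust estimation, a log2 fold change of at least 1, muscle, fat, blood and mitochondrial genes left out, each library left out in turn, and the replicate number as a block. Removal of the trend of log2 CPM on transcript length in each library, and leaving out the nephron lists and ribosomal protein genes, were added after the data were seen. No 2 libraries were copies of each other: between libraries of a group, a chi-square of the counts per degree of freedom ranged from 15.0 (double mutants 1 and 3) to 1205 (ApoE-/- 1 and 3), where sampling noise alone gives about 1.

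The steps were tested on simulated counts with the means and library sizes of this comparison (19127 genes, 3 against 3 libraries). Genes were drawn independently, with 1 dispersion per gene, estimated from the data and shared by both groups. Of 50 genes changed at each size, 4% were recovered at 2-fold, 68% at 4-fold, 82% at 8-fold and 90% at 16-fold, with 7 false among 136 calls. With no change simulated, 0 genes and 0 lists were called, and the shifted list was the 1 list called of 32. In the data the groups differed in spread (biological coefficient of variation 0.590 for ApoE-/- and 0.209 for double mutants). Genes of a list also moved together, with an estimated correlation of up to 0.981. The simulated false calls and list calls therefore do not give the error rates in these data.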

Results

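Aortas of mice without apolipoprotein E, the ligand by which remnant lipoproteins are cleared, were compared with aortas of mice that also lacked interleukin-16, a secreted cytokine that binds CD4. Both groups were fed a high-fat diet for 24 weeks from 8 weeks of age. The question was how the loss of interleukin-16 alters expression in the aorta after that diet. Each group had 3 samples. Read counts per gene were available for all 6, with 65730600 to 85568300 counts in the ApoE-/- libraries and 42862000 to 47208800 in the double mutant libraries. Whether the numbered samples came from separate animals is not given in the sources used here, so p-values measure only the spread between these samples, which may be technical.

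Il16 (ENSMUSG00000001741, GRCm38 chromosome 7, 83642825 to 83745726, minus strand) was at 28.3, 28.7 and 15.1 CPM in ApoE-/- 1, 2 and 3, and at 7.93, 12.1 and 12.2 CPM in double mutant 1, 2 and 3. All 3 double mutant libraries lay below all 3 ApoE-/- libraries. The log2 fold change was -1.16 (SE 0.32, n = 3 and 3), with an adjusted p of 0.163, which did not pass. The double mutant libraries still held 344, 578 and 525 counts of the gene. Which part of the gene is deleted in this line is not given in the sources used here. DESeq2 placed Il16 past the threshold (log2 fold change -1.18, adjusted p = 0.0267), as did limma-voom with sample weights (log2 fold change -1.28, adjusted p = 0.0243). Over 17 alternatives the adjusted p ran from 0.0243 to 0.493. Apoe (ENSMUSG00000002985, chromosome 7, 19696109 to 19699188, minus strand) was targeted in both groups. It was at 45.0, 24.9 and 20.9 CPM in the ApoE-/- libraries and rose to 138, 183 and 137 CPM in the double mutants (log2 fold change 2.34, SE 0.33, n = 3 and 3, adjusted p = 0.0369). Which part of Apoe is deleted is not given in the sources used here either, so counts over the whole gene check the genotypes only in part. The call for Apoe was lost without ApoE-/- 2 (adjusted p = 0.138), without ApoE-/- 3 (0.0638) and without any 1 of the double mutant libraries (0.194, 0.195 and 0.196), in a range over 17 alternatives of 3.92e-08 to 0.196.

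**Figure D1:**
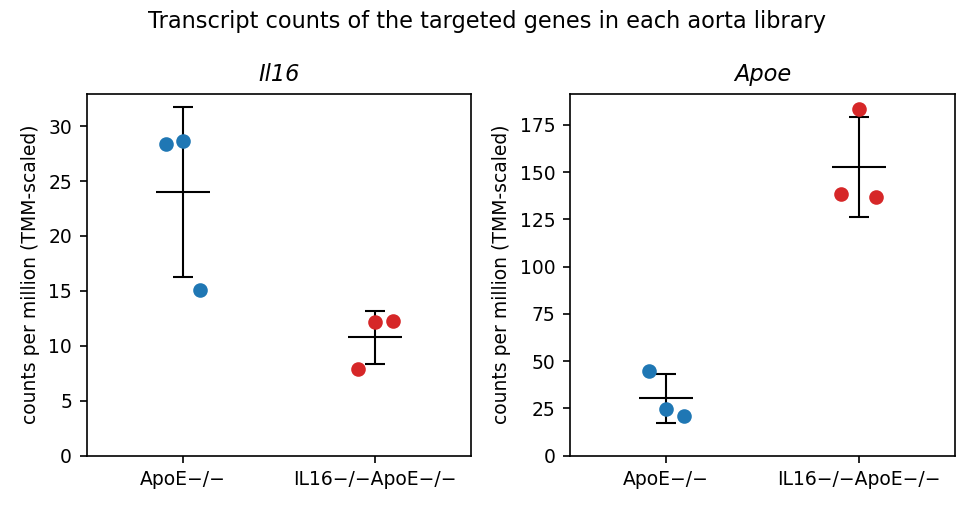
TMM-scaled CPM (vertical axes, from 0) of Il16 and Apoe in the 3 ApoE-/- libraries (blue points) and the 3 IL16-/-ApoE-/- libraries (red points), with the mean and SD of each group in black. Il16 lies between 7.93 and 12.2 CPM in the double mutants and between 15.1 and 28.7 CPM in ApoE-/-, and Apoe between 137 and 183 CPM against 20.9 to 45.0 CPM.

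The genes with the largest increase in the double mutants were genes known for expression in kidney tubules. Kap, encoding kidney androgen-regulated protein, was at 357, 349 and 389 CPM in the double mutant libraries and had no count in any ApoE-/- library, at least 28428-fold higher (365 ± 21.5 CPM, SD, n = 3, adjusted p = 0.00397). Umod, encoding uromodulin of the thick ascending limb, was at least 2439-fold higher (31.3 ± 1.28 CPM, SD, n = 3), and Slc12a1, the furosemide-sensitive cotransporter of the same segment, at least 1204-fold (15.5 ± 1.44 CPM, SD, n = 3). The other 7 were the proximal tubule enzymes Acsm2, Miox and Mep1a, the urate transporter Slc22a12, the glucuronosyltransferase Ugt2b38, the kallikrein Klk1 and the calcium-binding S100g. None of these 7 had a count in any ApoE-/- library. Their means in the double mutants ran from 8.34 CPM (S100g) to 39.2 CPM (Acsm2), and their bounds from at least 650-fold (S100g) to at least 3053-fold (Acsm2) higher. In lists of nephron markers added after these genes had been seen, 9 of 12 tested proximal tubule genes, 5 of 7 of the loop of Henle, 3 of 13 of the distal tubule and collecting duct and 0 of 8 of the podocyte rose, against 11, 6, 7 and 0 adjusted over the list alone. Of the 8 podocyte genes, 3 had all double mutant libraries above all ApoE-/- libraries. Among the other-organ lists, 0 of 9 tested liver genes, 0 of 3 of the adrenal cortex, 0 of 3 of lung epithelium, 0 of 1 of the exocrine pancreas and 0 of 6 thymocyte genes passed over all genes. Adjusted over the list alone, 2 thymocyte genes were higher, Rag1 and Tcf7, and 0 in the other 4 lists.

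In all, 226 genes rose and 12 fell in the double mutants among 19833 tested by edgeR's quasi-likelihood test, and 3154 had an unadjusted p under 0.05 (1760 higher, 1394 lower). Of the 226, 61 had no count in any ApoE-/- library. In 26.4% of tested genes all libraries of one group lay above all of the other. Libraries alike in spread would give 10% by chance. The groups differed in spread (biological coefficient of variation 0.590 and 0.209) and genes move together, so 10% is no fair mark for this share. The 5 genes with the largest fall under the rule for named genes were the imprinted zinc finger gene Peg3 (log2 fold change -1.38, SE 0.17, 82.5 to 114 CPM against 35.1 to 41.4 CPM, n = 3 each), the zinc finger genes Zfp942 (-1.09, SE 0.18) and Zfp991 (-0.88, SE 0.14), the nuclear export factor Nxt2 (-1.04, SE 0.16) and the GTPase-activating gene Arhgap5 (-0.94, SE 0.13). Their adjusted p ran from 0.0252 (Peg3) to 0.0475 (Zfp942). Zfp942, Nxt2, Arhgap5 and Zfp991 lost their calls without ApoE-/- 2 (adjusted p = 0.0649 to 0.131) and without ApoE-/- 3 (0.0551 to 0.0753), and all 5 with the trend of expression on transcript length removed (0.0577 to 0.0928). Zfp942 also lost its call with upper-quartile factors (adjusted p = 0.0516) and in limma-voom (0.0502), and Zfp991 with no filter (0.0641). With the length trend removed the log2 fold changes of the 5 were -1.18 (SE 0.22, Peg3), -1.06 (SE 0.17, Zfp942), -0.99 (SE 0.16, Nxt2), -0.77 (SE 0.12, Arhgap5) and -0.81 (SE 0.13, Zfp991). The other tools gave larger counts, with 1133 higher and 347 lower in DESeq2, 386 and 23 in limma-voom, and 1863 and 1488 in limma-voom with sample weights. Without ApoE-/- 1 the counts were 2651 and 2580, without ApoE-/- 2 they were 101 and 7, without ApoE-/- 3 they were 163 and 19, and without any 1 double mutant library both were 0, with 1920 to 2042 genes at an unadjusted p under 0.05.

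The libraries within a group were not alike in spread. The biological coefficient of variation was 0.590 among the ApoE-/- libraries and 0.209 among the double mutants. The Spearman correlation of log2 CPM across genes, which are not independent replicates, was 0.909 to 0.961 within ApoE-/- and 0.985 to 0.987 within the double mutants. With the double mutants it was 0.957 to 0.961 for ApoE-/- 1, 0.940 to 0.942 for ApoE-/- 2 and 0.912 to 0.918 for ApoE-/- 3. ApoE-/- 1 was thus closer to the double mutants than to ApoE-/- 2 (0.945) or ApoE-/- 3 (0.909). Over the 500 most variable genes it was 0.303 to 0.480 within ApoE-/- and 0.0206 to 0.108 between the groups. ApoE-/- 1 had 474 CPM of Xist, the RNA that coats the inactive X chromosome, and 0.143 CPM of the Y-linked Ddx3y. The other 5 libraries had 0.497 to 6.21 CPM of Xist and 70.1 to 136 CPM of Ddx3y. By these genes ApoE-/- 1 had a female pattern and the other 5 a male pattern, so sex was mixed in the ApoE-/- group, and sex is not given in the sources used here. Only the fits without ApoE-/- 1 compare libraries of the same sex pattern. In them 19 lists passed camera, but not the circadian clock (list adjusted p = 0.203), immediate early and heat shock (0.0546) and neutrophil (0.148) lists. All 238 genes called with every library in were also called without ApoE-/- 1, Dbp, Tef, Bhlhe41 and Fos among them. The clock list's median log2 fold change was 0.57, against 0.65 with every library in. Camera compares a list with all other genes, so a lost list call does not mean that its members lost their change. Sex and the other differences of ApoE-/- 1 cannot be told apart. Myh11, the smooth muscle myosin, was at 1158, 6355 and 8497 CPM in ApoE-/- 1, 2 and 3 and at 2328, 2031 and 2345 CPM in the double mutants. The fat-cell lipid carrier Fabp4 was at 3002, 365 and 426 CPM in ApoE-/- 1, 2 and 3 and at 3402 to 3635 CPM in the double mutants. Macrophage lysozyme Lyz2 was at 3561, 1750 and 259 CPM against 3527 to 5095 CPM.

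Of 32 lists, 16 passed camera with the preset correlation, 15 toward higher values in the double mutants and 1 toward lower. With an estimated correlation 0 of the 32 passed, fry's directional test passed 0 and fry's mixed test 6.

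By the preset-correlation p with all libraries in, cardiac muscle came first of the 32 lists. Of 12 tested members of the cardiac muscle list, 2 rose over all genes and 11 adjusted over the list alone. None fell, and all 12 had positive fold changes with a median log2 value of 3.05. Troponin T2 (Tnnt2) rose from 14.5 ± 3.25 to 53.7 ± 15.7 CPM (SD, n = 3 each, log2 fold change 1.89, SE 0.28, adjusted p = 0.0420). Sarcolipin (Sln), with 4 counts over the 3 ApoE-/- libraries, rose to 3.83 ± 1.64 CPM (adjusted p = 0.0439). Both lost their calls without ApoE-/- 2 (adjusted p = 0.152 and 0.0579), without ApoE-/- 3 (0.0583 and 0.0647) and with the length trend removed (0.106 and 0.0627), where their log2 fold changes were 1.61 (SE 0.32) and 7.39 (SE 1.20) against 1.89 (SE 0.28) and 7.60 (SE 1.16). Sln also lost its call in limma-voom with sample weights (adjusted p = 0.0528). The list passed at an adjusted p of 7.98e-13, but had an adjusted p = 0.609 with an estimated correlation. In the skeletal muscle list, 0 of 12 members passed over all genes and 10 adjusted over the list alone. The median log2 fold change was 4.49, and 2.98 without double mutant 3 (list adjusted p = 2.37e-06, and adjusted p = 0.691 with an estimated correlation). Among them, the fast myosin Myh4 was at 8.59, 2.16 and 51.8 CPM in double mutants 1, 2 and 3 against 0 to 0.274 CPM. Creatine kinase Ckm at 4.09 to 39.4 CPM against 0.961 to 3.20 CPM. Neither passed over all genes (adjusted p = 0.121 and 0.151). Of 12 Schwann cell and neuron genes, 0 passed over all genes and 5 were higher adjusted over the list alone. In 11 all double mutant libraries lay above ApoE-/-, and the median log2 fold change was 1.99 (list adjusted p = 2.37e-06, and adjusted p = 0.691 with an estimated correlation). Its first members by p were myelin basic protein Mbp (log2 fold change 1.44, SE 0.31, adjusted p = 0.103) and the glial S100b (1.91, SE 0.41, adjusted p = 0.104).

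Endothelial adhesion molecules, which capture leukocytes from the blood, were higher in the double mutants as a list. Of 7 tested members, 0 passed over all genes and 6 were higher adjusted over the list alone. Their list had a median log2 fold change of 0.82 (list adjusted p = 0.000192, and adjusted p = 0.691 with an estimated correlation). E-selectin (Sele) was at 13.4 to 21.4 CPM against 5.41 to 6.96 CPM (log2 fold change 1.48, SE 0.26, adjusted p = 0.0573). P-selectin (Selp) was at 72.7 to 87.1 against 21.6 to 45.8 CPM (1.19, SE 0.28, adjusted p = 0.121). Neither passed over all genes. The general endothelial list had 0 of 12 members past the threshold over all genes and 2 adjusted over the list alone. These were the sialomucin Emcn (log2 fold change 1.32, SE 0.31, adjusted p = 0.119) and the receptor Tie1 (0.89, SE 0.24, adjusted p = 0.154). Its median was 0.70, with a list adjusted p of 0.00122 and an adjusted p = 0.760 with an estimated correlation.

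The B cell, neutrophil, macrophage, foam cell, cytokine and iron lists had positive medians in the double mutants with few members past a threshold. In the B and plasma cell list, 0 of 12 members passed over all genes and 4 were higher adjusted over the list alone. Among them was the B cell receptor gene Cd79a (log2 fold change 2.35, SE 0.50, adjusted p = 0.102). The list median was 2.24 (list adjusted p = 5.63e-06, and adjusted p = 0.691 with an estimated correlation). In the neutrophil list, 0 of 11 passed over all genes and 2 adjusted over the list alone, the calprotectin genes S100a8 (2.04, SE 0.48, adjusted p = 0.120) and S100a9 (2.89, SE 0.69, adjusted p = 0.124). The list had an adjusted p of 0.0127, an adjusted p = 0.760 with an estimated correlation, and a list adjusted p of 0.148 without ApoE-/- 1. Of 18 macrophage and monocyte genes, 0 passed over all genes and 0 adjusted over the list alone. The median was 0.64 (list adjusted p = 0.0350, and adjusted p = 0.816 with an estimated correlation). The leading members were Tyrobp (2.11, SE 0.79, adjusted p = 0.281) and Cd68 (1.65, SE 0.75, adjusted p = 0.350). Of 16 foam cell and lipid uptake genes, 0 passed over all genes and 0 adjusted over the list alone. The list median was 0.61 (list adjusted p = 0.0127, and adjusted p = 0.760 with an estimated correlation). It was led by the fatty acid carrier Fabp5 (2.40, SE 0.62, adjusted p = 0.148) and the cholesterol-esterifying Soat1 (0.51, SE 0.29, adjusted p = 0.424). Of 21 cytokine and chemokine genes, 0 passed over all genes and 1 adjusted over the list alone. That 1 was the neutrophil attractant Cxcl1 (1.67, SE 0.28, adjusted p = 0.0529), followed by Cxcl2 (1.53, SE 0.37, adjusted p = 0.125). The median of that list was 0.65 (list adjusted p = 0.00728, and adjusted p = 0.760 with an estimated correlation). Of 14 ferroptosis and iron genes, 0 passed over all genes and 0 adjusted over the list alone. The median was 0.51 (list adjusted p = 0.0409, and adjusted p = 0.760 with an estimated correlation). At its top were the iron exporter Slc40a1 (1.03, SE 0.25, adjusted p = 0.129) and heme oxygenase Hmox1 (1.31, SE 0.50, adjusted p = 0.284). Without ApoE-/- 3, the library with the lowest mean of the macrophage list, the list calls were lost for macrophages (median 0.21, list adjusted p = 0.670), foam cells (0.19, adjusted p = 0.0906), cytokines (0.28, adjusted p = 0.146) and iron (0.19, adjusted p = 0.266). Without ApoE-/- 1 these 4 medians were 1.51, 1.19, 1.77 and 0.86. Without double mutant 2 they were lost for macrophages (0.0646) and iron (0.0608).

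The fat hormone leptin (Lep) was at 0.871 to 2.05 CPM in the ApoE-/- libraries and rose to between 18.7 and 22.0 CPM in the double mutants (n = 3 each, log2 fold change 3.90, SE 0.38, adjusted p = 0.0168). It was the 1 member of 14 in the adipocyte list to pass, over all genes as adjusted over the list alone. The list median was 0.64 (list adjusted p = 0.00236, and adjusted p = 0.760 with an estimated correlation). The median was 2.18 without ApoE-/- 1, 0.28 without ApoE-/- 2 and 0.20 without ApoE-/- 3, and Lep lost its call without ApoE-/- 2 (adjusted p = 0.0593). The list's mean log2 CPM was 8.59 in ApoE-/- 1, 6.32 and 6.04 in ApoE-/- 2 and 3, and 8.38 to 8.47 in the double mutants. Oxidative phosphorylation genes followed the same order of libraries, with 8.59, 6.79 and 6.59 in ApoE-/- and 8.35 to 8.48 in the double mutants. Of 16 such genes, 0 passed over all genes and 0 adjusted over the list alone. The median was 0.65 (list adjusted p = 0.00236, and adjusted p = 0.760 with an estimated correlation), and the call was lost without ApoE-/- 3 (median 0.27, list adjusted p = 0.0595). Without ApoE-/- 1 and without ApoE-/- 2 the median was 1.55 and 0.38. Cox4i1 (log2 fold change 1.41, SE 0.52, adjusted p = 0.273) and Ndufb8 (1.10, SE 0.54, adjusted p = 0.374) came first by p.

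**Figure D2:**
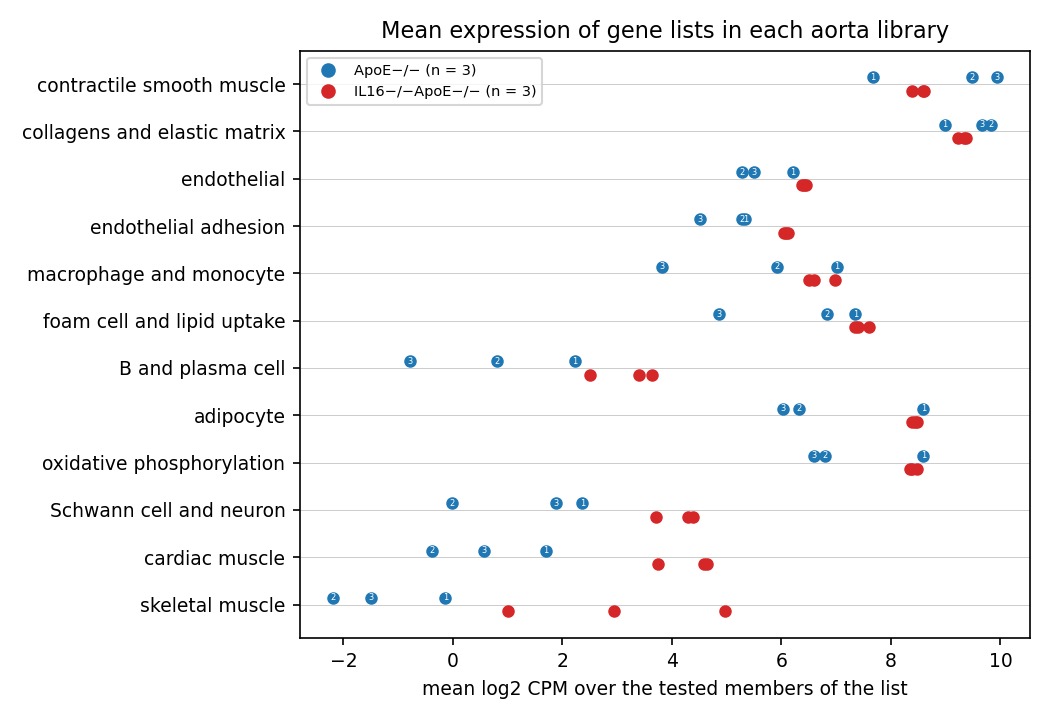
Mean log2 CPM over the tested members of 12 gene lists (horizontal axis) in each of the 3 ApoE-/- libraries (blue, numbered inside the points) and the 3 IL16-/-ApoE-/- libraries (red). The double mutant libraries lie close together in most lists, as in the adipocyte list at 8.38 to 8.47, while ApoE-/- 1, 2 and 3 are at 8.59, 6.32 and 6.04.

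Contractile smooth muscle was the 1 list of 32 that passed toward lower values in the double mutants. Of 16 members, 0 passed over all genes, 0 passed adjusted over the list alone and 15 had negative fold changes. Their median log2 value was -0.84 (list adjusted p = 0.0242, and adjusted p = 0.760 with an estimated correlation). The double mutants, with a mean log2 CPM of 8.39 to 8.60, lay between ApoE-/- 1 at 7.68 and ApoE-/- 2 and 3 at 9.47 and 9.93. Synpo2 (log2 fold change -1.49, SE 0.71, adjusted p = 0.365) and the smooth muscle coactivator Myocd (-1.29, SE 0.64, adjusted p = 0.375) came first by p. The call was lost without ApoE-/- 2 (list adjusted p = 0.114), ApoE-/- 3 (0.591) or double mutant 2 (0.0503). The median was -1.28 without ApoE-/- 1 and -0.30 without ApoE-/- 3.

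Clock genes moved in both directions. Of 15 tested members of the circadian clock list, 3 rose over all genes and 0 fell, while adjusted over the list alone 8 were higher and 4 lower. The PAR-domain transcription factors Dbp (6.76 ± 2.53 to 74.4 ± 12.5 CPM, SD, n = 3 each, log2 fold change 3.46, SE 0.32, adjusted p = 0.0151) and Tef (1.17, SE 0.17, adjusted p = 0.0373) and the repressor Bhlhe41 (1.28, SE 0.14, adjusted p = 0.0209) rose. Ciart, Nr1d1, Per3, Hlf and Nr1d2 were higher and the activators Arntl, Clock and Npas2 and the repressor Cry1 were lower in all 3 double mutant libraries than in any ApoE-/- library. Their adjusted p over all genes ran from 0.0648 (Ciart) to 0.154 (Nr1d2). Per1, Per2 and Cry2 overlapped between the groups. Without ApoE-/- 2 the calls of Bhlhe41 (adjusted p = 0.0545), Tef (0.117) and Fos (0.0653) were lost, and without ApoE-/- 3 that of Tef (0.0705). The list passed at an adjusted p of 0.0102, had an adjusted p = 0.691 with an estimated correlation, and lost its call without ApoE-/- 1 (list adjusted p = 0.203). Fry's mixed test, which allows for both directions, gave an adjusted p of 0.0101. The immediate early gene Fos rose from 18.6 ± 3.66 to 75.1 ± 12.2 CPM (SD, n = 3 each, log2 fold change 2.02, SE 0.21, adjusted p = 0.0203). Of 12 members of the immediate early and heat shock list, 1 rose over all genes and 6 adjusted over the list alone. That list had a median of 0.62, a list adjusted p of 0.000696, an adjusted p = 0.691 with an estimated correlation, and a list adjusted p of 0.0546 without ApoE-/- 1.

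**Figure D3:**
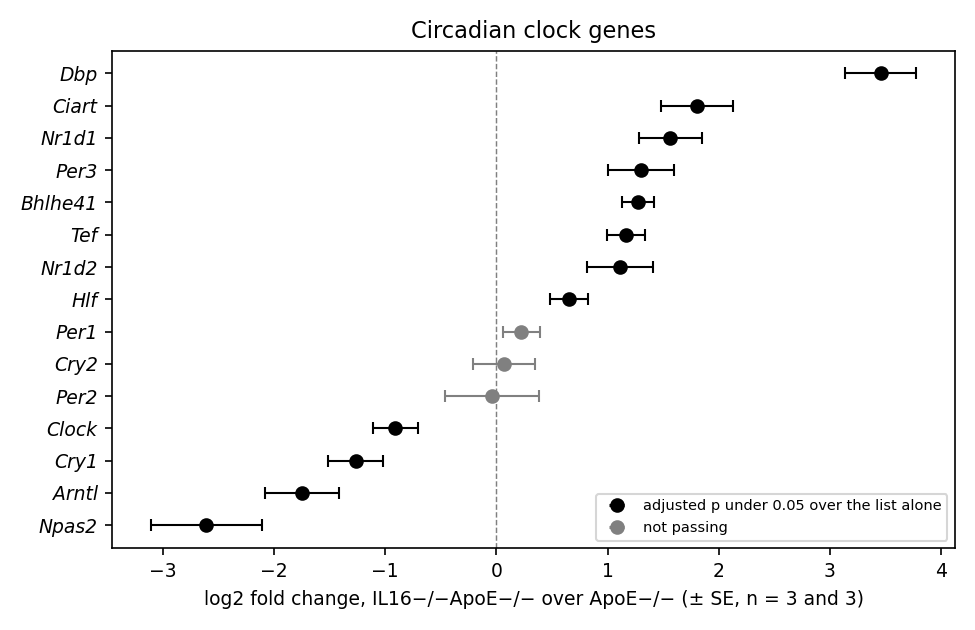
Log2 fold change of the 15 circadian clock genes in IL16-/-ApoE-/- over ApoE-/- libraries (horizontal axis, points with SE, n = 3 in each group), in black where the p adjusted over the list alone passed 0.05 and in grey where it did not. Dbp is highest at 3.46, and 5 genes lie below 0, of which Npas2, Arntl, Cry1 and Clock passed over the list alone and Per2 (-0.04) did not.

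The other 16 lists did not pass in the main fit, and 12 of them passed under at least 1 alternative. Some passed toward higher values with all 6 libraries in. In limma-voom these were T cells and modulated smooth muscle (list adjusted p = 0.0220 each), brown fat (0.0280), matrix proteases (0.0419), fatty acid oxidation and synthesis (0.0447) and MHC class II (0.0451). With no filter the same lists passed, as did erythroid cells and platelets (0.0298). Matrix proteases and inhibitors came nearest (list adjusted p = 0.0514), with 0 of 18 members past the threshold over all genes and 2 adjusted over the list alone. These were the protease inhibitor Timp1 (log2 fold change 2.53, SE 0.49, adjusted p = 0.0820) and the aggrecanase Adamts5 (-1.08, SE 0.23, adjusted p = 0.1002). Brown fat thermogenesis (list adjusted p = 0.0629) was led by Cox7a1 (3.43, SE 0.91, adjusted p = 0.154) and Cox8b (3.22, SE 0.99, adjusted p = 0.206), and modulated smooth muscle (list adjusted p = 0.0814) by the cartilage protein genes Chad (1.52, SE 0.34, adjusted p = 0.107) and Comp (0.36, SE 0.14, adjusted p = 0.296). In both lists, of 12 and 17 tested members, 0 passed over all genes and 0 adjusted over the list alone. Cholesterol synthesis (0.115) had 0 of 16 members past the threshold over all genes and 2 lower adjusted over the list alone, among them the isomerase gene Idi1 (log2 fold change -0.86, SE 0.20, adjusted p = 0.121). Collagens and elastic matrix (0.115) had 0 of 20 past either threshold, with the crosslinking enzymes Loxl1 (-0.61, SE 0.24, adjusted p = 0.291) and Lox (-0.86, SE 0.34, adjusted p = 0.295) first by p. List adjusted p was 0.104 for T cells, 0.115 for erythroid cells and platelets, 0.137 for MHC class II, 0.195 for fatty acid oxidation and synthesis, 0.390 for NK cells, 0.425 for the inflammasome, 0.484 for fibroblasts, 0.705 for the cell cycle and 0.926 for the interferon response. No member of these 9 lists passed over all genes or adjusted over the list alone. The median of the NK list was -1.02, 0.46 without ApoE-/- 1 (list adjusted p = 0.563) and -1.58 without ApoE-/- 3 (0.00150). Without ApoE-/- 1, list tests passed toward higher values for brown fat (list adjusted p = 3.12e-10), fatty acid oxidation and synthesis (1.09e-07), MHC class II (0.0173), T cells (0.0353) and the inflammasome (0.0477), and toward lower values for collagens (0.000214). Without ApoE-/- 2 they passed toward higher values for modulated smooth muscle (0.000411), matrix proteases (0.0113) and T cells (0.0449). Without ApoE-/- 3 they passed toward lower values for NK cells, the interferon response (0.00595) and the cell cycle (0.0322). Without 1 double mutant library they passed toward higher values for brown fat (0.0361 to 0.0395, each of the 3), matrix proteases (0.0178 without 1, 0.0370 without 3), modulated smooth muscle (0.0377 without 1) and erythroid cells and platelets (0.0157 without 1). Of the IL-16 receptors and partners (list adjusted p = 0.773), the receptor Cd4 was at 11.8 to 19.4 CPM in the double mutants against 1.45 to 9.52 CPM (log2 fold change 1.38, SE 0.63, adjusted p = 0.350). None of the 5 tested members passed over all genes or adjusted over the list alone.

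Genes near Il16 were called about as often as the rest of the genome. Within 10 Mb of Il16, 2 of 158 tested genes were called, among them Rhcg, against 236 of 19646 elsewhere (odds ratio 1.05, 95% interval 0.126 to 3.92, Fisher's exact p = 0.715). A list of 16 genes set in advance as Il16 neighbours did not pass (list adjusted p = 0.567). In it 0 members passed over all genes and 1 adjusted over the list alone, Mthfs (log2 fold change 0.91, SE 0.20, adjusted p = 0.104), followed by Saxo2 (-0.98, SE 0.40, adjusted p = 0.301). Mthfs was not among the genes at an unadjusted p under 0.05 within 10 Mb of Il16. It therefore lies outside that window, and the list is not one of the nearest genes.

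Many of the genes that rose had short transcripts. Of the 226, 105 had a median annotated transcript under 1000 bases, as had 3184 of the 19833 tested genes, and 63 were pseudogenes, whose counts can include reads of their parent genes. Of 78 ribosomal protein genes, a class looked at after the calls had been seen, 14 rose and 0 fell, led by Rps29 (log2 fold change 3.30, SE 0.36, adjusted p = 0.0208) and Rpl38 (3.26, SE 0.24, adjusted p = 0.00745). The 39 with transcripts of at most the class's median length of 772.5 bases had a median log2 fold change of 1.36, and 13 of them rose. The 39 longer ones had a median of 0.33, and 1 rose. Among all tested genes with a mean of at least 1 CPM, the median log2 fold change went from 1.25 below 500 bases (384 genes) to 0.35, 0.05, -0.11 and -0.24 in the successive length classes up to 1000, 2000, 4000 and over 4000 bases. With the trend of expression on transcript length removed from each library, 143 genes rose and 21 fell, and 146 of the 238 called genes were called in both fits.

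**Figure D4:**
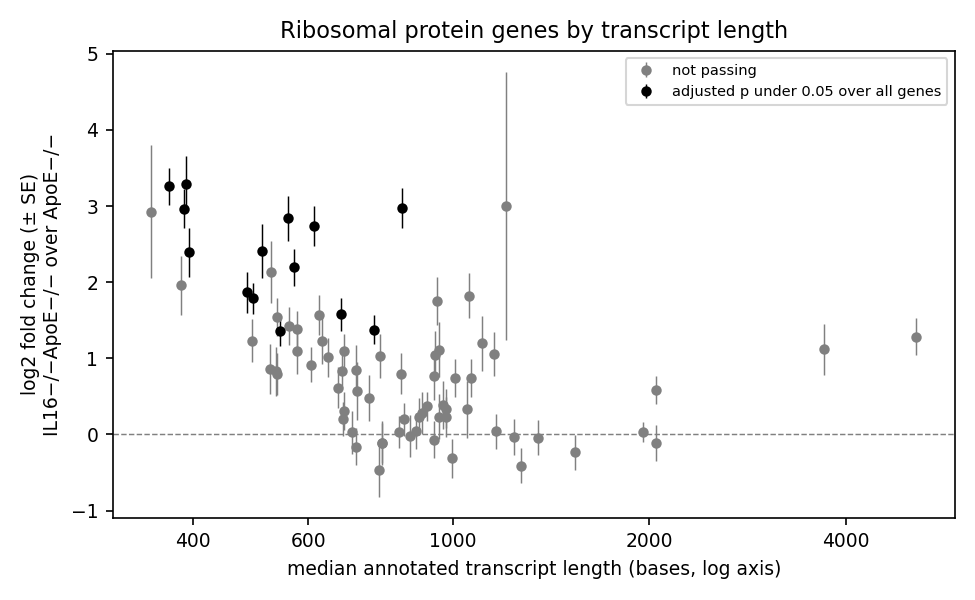
Log2 fold change with SE (vertical axis, IL16-/-ApoE-/- over ApoE-/-, n = 3 in each group) of the 78 ribosomal protein genes against their median annotated transcript length in bases (horizontal log axis), in black where the adjusted p over all genes passed 0.05. Of the 14 genes that passed, 13 have transcripts of 772.5 bases or less.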

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

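For the named genes and the 16 lists that passed, 284 gene values and 208 list values kept their direction and their side of the threshold under an alternative, 122 gene and 45 list values lost a call without turning direction, and 2 gene values gained one. The named genes counted here are Il16, Apoe, the genes with the largest changes under the rule and the list members past the threshold over all genes. List members named as not passing are left out of this tally. For the 16 lists that did not pass, 47 of 253 list values gained a call, in 12 lists. Counts of 226 higher and 12 lower genes became 1133 and 347 in DESeq2, 386 and 23 in limma-voom and 1863 and 1488 in limma-voom with sample weights, and the cause was not tested. Leaving out 1 library at a time gave 0 to 2651 higher and 0 to 2580 lower genes. The count was 0 whenever a double mutant library was left out (edgeR, with 1920 to 2042 at an unadjusted p under 0.05). With the replicate block, edgeR called 0 higher and 0 lower genes (2327 at an unadjusted p under 0.05). Same-numbered libraries did not deviate together (correlations -0.0400, -0.0271 and -0.00950), so these values show no pairing by number. They cannot exclude one, because the large differences among the ApoE-/- libraries, as in sex pattern and Myh11, could hide it. With the length trend removed the counts were 143 and 21. With nephron and ribosomal protein genes left out, 147 genes were higher and 8 lower. Of the 226, only 17 were in a nephron list and 14 were ribosomal protein genes, so other genes lost their calls as well. The removal of the length trend and the leaving out of these genes were both chosen after the data were seen. The other scalings, filters and moderation gave 225 to 272 higher and 10 to 15 lower genes. Il16 gained a call in DESeq2 (log2 fold change -1.18) and limma-voom with sample weights (-1.28). Apoe kept its direction, at 2.12 to 2.74 when 1 library was left out, and lost its call with the replicate block (2.41, adjusted p = 0.179, in a range of 3.92e-08 to 0.196). The 16 lists passing became 13 to 23 across scalings, filters, tools, left-out libraries and the block, and 0 with an estimated correlation or with fry's directional test. The odds ratio for genes near Il16 was 1.05 within 10 Mb, 1.59 within 5 Mb, 0.778 within 20 Mb and 0.900 at an unadjusted p under 0.05, with Fisher's exact p of 0.365, 1 and 0.743 for the last 3. The median Spearman correlation between libraries fell to 0.323 within ApoE-/- and 0.721 within the double mutants over the 500 most variable genes, a set chosen for its spread. At this depth, with 1 dispersion per gene for both groups, simulated 2-fold changes were recovered in 4% of cases. Changes of that size were thus mostly not detectable at such a spread.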

Other observations

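The tests of the hours of the day and of a length trend shared by all genes were chosen only after their results had been seen, and the organ marker lists and the genes named in the next paragraphs after the largest changes had been seen.

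Mgp, the matrix Gla protein that inhibits calcification, was at 456, 534 and 634 CPM in ApoE-/- and 1936, 2026 and 2061 CPM in the double mutants (log2 fold change 1.89, SE 0.27, adjusted p = 0.0364). The calcium-binding S100a4 (2.43, SE 0.36, adjusted p = 0.0389), S100a6 (1.72, SE 0.15, adjusted p = 0.0125) and the galectin Lgals1 (1.64, SE 0.20, adjusted p = 0.0248) rose as well, and all 4 have transcripts of 800 bases or less. Genes with a mean of at least 1 CPM had a median log2 fold change of 1.25 below 500 bases and 0.35 from 500 to 1000 bases. Values of these 4 with the length trend removed are not given here, so their rises are not separated from that trend. Among genes with longer transcripts, the BMP antagonist Grem1 (1.87, SE 0.27, adjusted p = 0.0373), the stretch-responsive Ankrd1 (1.04, SE 0.16, adjusted p = 0.0443) and paraoxonase Pon1 (1.80, SE 0.24, adjusted p = 0.0304) rose.

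The lung surfactant gene Sftpc was at 8.81 and 15.8 CPM in ApoE-/- 1 and 2, and at 0 to 0.0931 CPM in ApoE-/- 3 and the double mutants. Alb, the liver's albumin, was at 43.5 CPM in ApoE-/- 2 and at 0 to 2.79 CPM in the others. The cytotoxic granule gene Gzmb was at 19.0 CPM in ApoE-/- 1, at 4.805 CPM in ApoE-/- 2 and at 0.298 to 0.777 CPM in ApoE-/- 3 and the double mutants. Rag1, a recombinase gene of immature lymphocytes, was at 1.91 to 2.82 CPM in the double mutants against 0 to 0.316 CPM (log2 fold change 4.29, SE 1.24, adjusted p = 0.181).

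The real split of the 6 libraries called 238 genes, and the 9 other splits into 3 and 3 called 0 each by edgeR (83 to 1817 at an unadjusted p under 0.05), so 1 of 10 splits gave as many, which is too few splits for a share under 0.05.

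Kidney transcripts were present in all 3 double mutant libraries at an even level: proximal tubule and loop markers summed to 591 ± 28.0 CPM (SD, n = 3) against 9.08 ± 4.26 CPM in ApoE-/-, beside 384 ± 43.2 CPM for Schwann cell and neuron, 411 ± 141 for cardiac muscle, 413 ± 159 for B cell and 214 ± 220 for skeletal muscle markers in the same double mutant libraries. RNA from whole kidney stays open: 63.6% of 22 detected distal tubule, collecting duct and podocyte markers lay above all ApoE-/- libraries (exact 95% interval 40.7% to 82.8%), short of the 75% set in advance, and some podocyte markers, such as Npnt at 99.1 to 1097 CPM in ApoE-/-, are expressed in the aorta itself. A change of the aorta's own cells with genotype needed 2 of the 4 nephron lists under 25%, and none was. Of detected members, 91.7% (proximal tubule), 75% (loop), 78.6% (distal tubule and collecting duct) and 37.5% (podocyte) lay above all ApoE-/- libraries. For the tubule markers these shares argue against a change limited to a single nephron segment. A change of the aorta's own cells that reaches several segments' genes also stays open. Carry-over from other organs stays open too: 11.4% of 35 detected markers of 5 other organs lay above (exact 95% interval 3.20% to 26.7%). The thymocyte list reached 57.1%, and the liver, adrenal cortex, lung and pancreas lists 0% each. ApoE-/- 1 or 2 carried lung and liver transcripts that could hide such a share, though Sftpc and Alb themselves were low in the double mutants. The liver list's mean log2 CPM was 0.94 to 1.40 in the double mutants and -0.61, 2.34 and -2.68 in ApoE-/- 1, 2 and 3. In the lists of cardiac muscle, skeletal muscle and Schwann cells and neurons 11, 10 and 11 of 12 genes lay above. Reads passed between libraries sequenced together were not tested.

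The higher counts of short ribosomal protein genes may come in part from a length bias between the library sets, since across the 78 genes the Spearman correlation of log2 fold change with transcript length was -0.55 (bootstrap 95% interval -0.72 to -0.36, permutation p = 1e-05, the smallest its resamples can give). With the trend of all genes removed, the median log2 fold change of the shorter 39 went from 1.36 to 0.56, that of the longer 39 from 0.33 to -0.00390, and 9 of the 14 called genes still passed. In that fit the shorter 39 exceeded 465 other protein-coding genes in their length range by a median of 0.45 (bootstrap 95% interval over genes, taken as independent, 0.12 to 0.76). In these libraries that argues against the trend of all genes as the whole cause for the shorter 39. The 465 were matched on length and not on expression, and the interval leaves out the spread between libraries. Across the 78 genes a Spearman correlation of -0.33 with length remained after the removal. A rise of the class as a whole stays open, as the longer genes had a median 0.242 of that of the shorter ones (bootstrap 95% interval 0.0351 to 0.602). Genotype and library preparation cannot be told apart for this class, because the preparation of each library is not given in the sources used here.

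In the clock list, 12 of 15 members had all libraries of a group on one side, 8 of them higher, with Dbp, and 4 lower, with Arntl, while Per1, Per2 and Cry2 overlapped. The aortas of the groups may have been taken at different hours of the day, but the sides were sorted by phase after the values had been seen, so this count does not test it. A shift of the clock with genotype would give the same sides, so the hour and the genotype cannot be told apart, and collection times are not given in the sources used here. With the length trend of all genes removed, the median size of the changes of the 12 was 1.09 times as large (1.41 against 1.29 on the log2 scale, bootstrap 95% interval of the ratio over these genes 0.954 to 1.11). That trend was small where Dbp, Tef and Bhlhe41 lie, with medians of 0.05, -0.11 and -0.24 in the length classes above 1000 bases. Its removal could thus alter these changes little, and only the trend shared by all genes is argued against as their cause.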
